A study of Mus musculus with 36 samples.

How the data were processed

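R1 cells, an established line of mouse embryonic stem cells, were profiled before differentiation (day 0) and at days 3, 5 and 7 of differentiation without leukemia inhibitory factor (LIF), the cytokine that keeps such cells undifferentiated. Per the labels, the cells differentiated as embryoid bodies (aggregates kept from attaching), on 0.1% gelatin, or on 0.1% Matrigel, a basement membrane extract. This gave 10 groups of 3 samples. The replicates are separate experiments, numbered 1, 4 and 6 in the labels, so the p-values measure the spread between experiments. Each sample was hybridized in Cy3 (green) against a common reference RNA in Cy5 (red) on Agilent dual-colour mouse arrays. The 36 arrays cover 30 biological samples, and 6 are technical repeats. The reference RNA is not fully described in the sources used here, so values are ratios to it and only differences between groups are interpreted. The source names of 2 day 7 samples (replicate 6 on gelatin and replicate 4 on Matrigel) give day 5, while their other labels give day 7; they were kept as day 7, and an alternative left them out.

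Per the file headers, each array file holds scanner intensity values (mean spot signal and median local background in both channels), written by Agilent Feature Extraction version A.7.5.1, or A.7.1.1 for 9 arrays, all of them first arrays of experiment 1. The deposited files also hold a log10 ratio of red over green, background subtracted and dye normalized by that software. Other columns are flags of 0 or 1 for spots well above background, saturated, non-uniform or marked by hand. The deposited series matrix holds log2 values of the authors, whose normalization is not given in the sources used here. Over the genes of an array these values correlated with the ratios computed here at r between 0.857 and 0.967, and their medians per array lay between -0.102 and 0.0361. Both the log10 and the log2 values gave alternatives only.

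The intensities were processed with limma 3.58.1 in R 4.3.3, with the packages statmod 1.5.0 and data.table (version 1.17.8). Signals were background corrected by the normexp method with an offset of 50, normalized by loess within each array, and turned to log2 of sample over reference. Spots marked as outliers or by hand were set to missing, which removed 0.949% of probe values, and spots of the same probe were averaged. Of 20868 probes, 20554 were well above background in the green channel on at least 3 arrays and were kept. Technical repeats were averaged, and each gene was represented by its brightest probe. This left 20401 genes, of which 9711 had a symbol. Probes were named through the accession they carry, their description or an older symbol; 10908 probes had no symbol through these sources, among them any probe for Nanog, and stayed under their accession. Genome positions were not used here.

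Signal over background varied by array. The share of spots well above background in the green channel lay between 77.6% and 97.3% (median 91.2%), and at most 27 green spots of an array were saturated. The number of arrays limits the precision of every value.

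A linear model over the 10 groups with a shared, moderated spread (limma) gave each comparison, with Benjamini-Hochberg adjustment over the genes of that comparison and an adjusted p under 0.05 as the threshold. Errors of differences are standard errors of that model, and errors of group means are SDs over the 3 experiments. The comparisons were each condition at each day with day 0, conditions with each other on each day and in the mean of days 3, 5 and 7, day 7 with day 3 in each condition, and an F-test of the condition by day interaction. The labels give the experiment number of each sample, but the main fit has no block for it, since the authors' analysis is not given in the sources used here; a fit with that block was the paired alternative. The same experiment number did pair samples: over 135 pairs of groups, the residuals of same-number samples correlated at a median r of 0.37 across genes (range -0.2 to 0.71, with 115 pairs above 0.1), those of different numbers at -0.18, and 29 of 30 samples had their best partner in their own experiment. Genes are not independent replicates here. Values of the block are given where they change a call or move a count by more than 1.5 times.

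The 23 gene lists were fixed before the data were examined, as were the comparisons, threshold, naming rule and alternatives unless stated otherwise. The lists cover pluripotency, LIF and STAT3 targets, epiblast, primitive streak and early mesoderm, extraembryonic endoderm regulators, visceral endoderm, parietal endoderm and basement membrane, neural genes, cardiac muscle, blood and endothelium, mesenchyme and smooth muscle, fibroblast (feeder) markers, macrophage markers, Hox genes, trophoblast, germ cells, hypoxia and glycolysis, the cell cycle, p53 targets and cell cycle inhibitors, adhesion and contractility, stress response, imprinted genes, and cholesterol synthesis. The camera test with a preset correlation of 0.01 between genes compared each list with the other genes in 6 comparisons, adjusted over all 138 tests. It was repeated with the correlation estimated from each list. Of 55 tests past the threshold, 19 also passed this way. The fry test, whose directional p tests whether a list moved on balance to 1 side and whose mixed p tests change in either direction, does not compare a list with other genes; it called 57 and 60 tests. Members with a missing value in any sample took no part in camera but count as members. Median, mean and test of a list differed in sign in 18 tests, 0 of which passed the threshold.

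Named genes had a symbol and an adjusted p under 0.05. For day 7 against day 0, the 5 largest rises and 5 largest falls with non-overlapping groups were named. Chance alone gives non-overlap in 10% of genes at 3 against 3. For each mean over days, the 8 highest and 8 lowest differences with 1 sign on all 3 days were eligible, and for single-day comparisons between conditions and for day 7 against day 3 the 3 highest and 3 lowest with non-overlapping groups. For the interaction the rule allowed the 6 smallest p-values. Of each list, up to 4 members that passed, with the largest changes, were eligible, or up to 2 values where fewer than 2 had passed. Of these the text names chiefly members whose call held whichever sample was left out, a choice made after the values were seen. Pou5f1, Nanog, T, Gata4, Afp and Sox1 were stage markers in every group. A fold against a group in which a probe was not well above background on any array is given as a lower bound ("at least").

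Alternatives, changing 1 choice at a time, were the Feature Extraction log ratio, the series matrix values, no background subtraction, median centring in place of loess, no filter and a strict filter on dim probes, a change of at least 2-fold, the experiment number as a block, the extraction session as a block with the sample as a random effect, the first array only, the mean of all probes of a gene, leaving out the samples with conflicting labels, leaving out each sample in turn, an estimated correlation in camera, and fry. An alternative without 2 doubted repeat arrays, and 1 with the session as a block and without them, were added after the data were seen. List tests with the session as a block took the arrays as independent.

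The steps from normalized values to calls were tested on simulated data with independent noise at the spread of each gene, so without correlation between genes, in 10 simulations of 200 changed genes among 20401, 50 at each fold. For embryoid bodies at day 7 against day 0, 67.8%, 87.4%, 96.8% and 98.2% of genes changed 1.5, 2, 3 and 4-fold were recovered, with 5.45% false calls. For embryoid bodies against gelatin at day 3 the shares were 62.2%, 86.4%, 96.8% and 97.8% with 4.83% false calls, and for the mean over days 91%, 97.8%, 99.8% and 99.8% with 5.64%. In these simulations 0 calls had the wrong direction. A blood and endothelium list shifted by 0 was called in 0 of 10 simulations, and shifted by 0.25 or 0.5 (log2) in 10 of 10, with 0 calls of other lists. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.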

Results

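Pou5f1, the transcription factor that maintains pluripotency, stood at 1.88 ± 0.61 over the reference at day 0 (log2, SD, n = 3). By day 7 it had fallen against day 0 in embryoid bodies (-2.51 ± 0.36, adjusted p = 5.21e-05), on gelatin (-2.35 ± 0.36, adjusted p = 0.00017) and on Matrigel (-2.37 ± 0.36, adjusted p = 0.000165). At day 5 the fall had passed the threshold in embryoid bodies (-2.25 ± 0.36, adjusted p = 0.000274, but 0.0637 with the session as a block) and on Matrigel (-1.24 ± 0.36, adjusted p = 0.0377), but not on gelatin (-1.03 ± 0.36, adjusted p = 0.122), and at day 3 in no condition. The Matrigel call ended without any of 5 samples (adjusted p up to 0.209, without replicate 6 of day 0) and in 5 other settings (up to 0.455 with the session as a block). The condition by day interaction passed for neither Pou5f1 nor T. T (brachyury), the transcription factor of the primitive streak, passed at day 5 on gelatin (2.35 ± 0.68, adjusted p = 0.0494) and on Matrigel (2.72 ± 0.68, adjusted p = 0.0145). The gelatin call ended without any of 5 samples (up to 0.19, without replicate 6 of day 0) and in 3 other settings (up to 0.131 with median centring), and the Matrigel call without replicate 6 of day 0 (0.0704) or replicate 4 of Matrigel day 5 (0.0652). In embryoid bodies T was higher at day 3 without passing (2.09 ± 0.68, adjusted p = 0.144), with -0.83, 1.73 and 2.54 over the reference in experiments 1, 4 and 6. Gata4 and Afp, genes of endoderm, and Sox1, a gene of the early neural plate, passed against day 0 in 0 of 9 groups. Their largest differences were -0.10 for Gata4 and 0.28 for Afp on gelatin, at day 3 and day 5, and 0.09 for Sox1 in embryoid bodies at day 5. Nanog could not be located through the names used here.

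**Figure D1:**
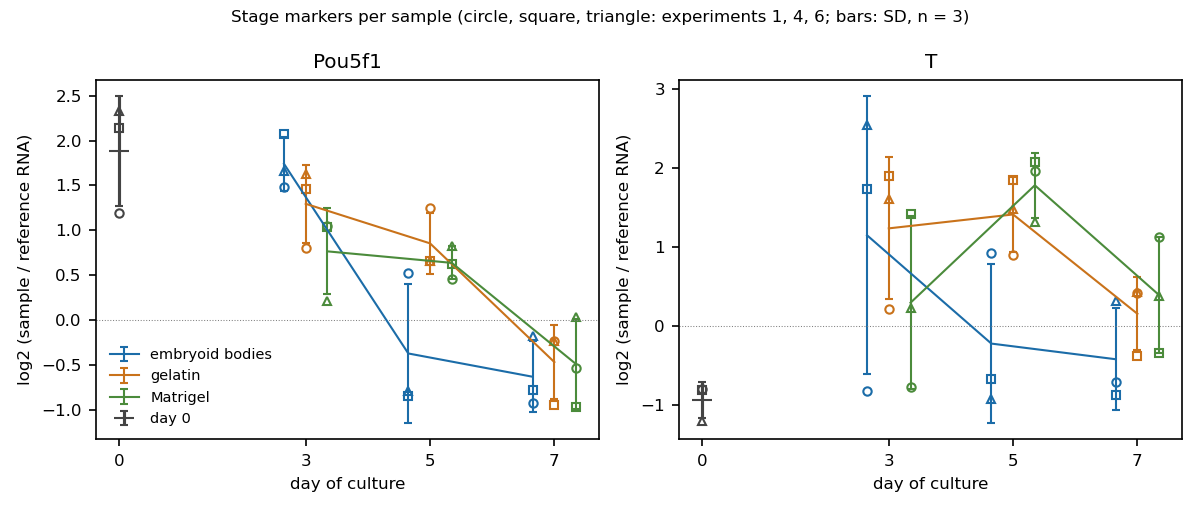
Log2 of sample over reference (vertical axis) by day of differentiation (horizontal axis, days) for the stage markers Pou5f1 and T. Embryoid bodies, gelatin and Matrigel are shown, with points for the 3 experiments and lines and bars for mean and SD. Pou5f1 started at 1.88 ± 0.61 and ended at -0.63 ± 0.40 in embryoid bodies, -0.47 ± 0.41 on gelatin and -0.49 ± 0.50 on Matrigel.

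Embryoid bodies at day 7 against day 0 showed which programmes replaced the undifferentiated state in aggregates. Globin genes of the first red blood cells of the embryo rose, Hbb-bh1 by 6.01 ± 0.86, adjusted p = 8.19e-05 and Hba-x by 4.32 ± 0.53, adjusted p = 7.92e-06 (log2, standard error). So did genes of the extracellular matrix of connective tissue, Postn (5.03 ± 0.58, adjusted p = 5.05e-06) and Col1a2 (3.88 ± 0.44, adjusted p = 2.69e-06), and the fetal growth factor Igf2 (3.85 ± 0.60, adjusted p = 0.000158, but 0.0633 with series matrix values). The largest falls were in genes that mark undifferentiated embryonic stem cells, Zfp42 (-4.42 ± 0.31, adjusted p = 8.67e-09) and Dppa5a (-4.20 ± 0.62, adjusted p = 6.19e-05). Tdh, an enzyme of threonine breakdown on which such cells depend (-3.93 ± 0.31, adjusted p = 3.17e-08), and Spp1, a secreted phosphoprotein (-3.87 ± 0.37, adjusted p = 3.18e-07), fell as well. Morc1, which silences transposons in male germ cells, fell (-3.56 ± 0.23, adjusted p = 1.95e-09) and was well above background on only 2 of 5 arrays of these embryoid bodies. All 10 genes moved the same way in 3 of 3 experiments, and each call held whichever sample was left out.

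On gelatin the 5 largest rises by day 7 included genes of the cytoskeleton and of membranes. Pmp22, a membrane protein of junctions and myelin, rose most (4.09 ± 0.74, adjusted p = 0.000767), with Vim, the intermediate filament of mesenchyme (3.36 ± 0.71, adjusted p = 0.00365), and Krt18, a keratin of simple epithelia (3.04 ± 0.55, adjusted p = 0.000832). Igf2 (3.43 ± 0.60, adjusted p = 0.000699) and Ppic, a prolyl isomerase (3.05 ± 0.62, adjusted p = 0.002), rose as well. Zfp42 (-3.57 ± 0.31, adjusted p = 1.79e-07), Tdh (-3.30 ± 0.31, adjusted p = 3.53e-07), Dppa5a (-3.23 ± 0.62, adjusted p = 0.0012) and Morc1 (-3.22 ± 0.23, adjusted p = 8.69e-09) fell here too. So did Slc7a3, a transporter of cationic amino acids (-3.17 ± 0.39, adjusted p = 1.2e-05). Morc1 was well above background on 2 of 3 of these arrays. On Matrigel the rises were led by a gene induced by interferon, the ubiquitin-like modifier Isg15 (3.53 ± 0.59, adjusted p = 0.000395). Rtp4, another interferon-induced gene (2.56 ± 0.40, adjusted p = 0.000175), Pmp22 (3.32 ± 0.74, adjusted p = 0.0047), the keratin Krt8 (2.76 ± 0.60, adjusted p = 0.0042) and the signal Wnt6 (2.45 ± 0.44, adjusted p = 0.00084) followed. The falls were Zfp42 (-3.29 ± 0.31, adjusted p = 5.49e-07), Tdh (-3.11 ± 0.31, adjusted p = 9.23e-07), Morc1 (-3.06 ± 0.23, adjusted p = 2.41e-08), Slc7a3 (-2.96 ± 0.39, adjusted p = 3.11e-05) and Tdrd12, a germ-line gene of small RNA pathways (-3.05 ± 0.40, adjusted p = 3.77e-05). In both conditions all 10 genes moved the same way in every experiment that measured them, and each call held whichever sample was left out.

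Genes of the undifferentiated state fell in every condition by day 7. Of 20 pluripotency genes, 0 rose, 16 fell and 4 did not pass in embryoid bodies, 0, 14 and 6 on gelatin, and 0, 14 and 6 on Matrigel (adjusted over the list alone, 17, 16 and 17 lower). The medians were -1.32, -1.36 and -1.29, with adjusted p = 5.33e-16, 2.4e-15 and 5.33e-16. Nr0b1, a nuclear receptor of the pluripotency network measured in 2 of the experiments, fell in embryoid bodies (-3.06 ± 0.30), and Klf2, a factor of naive pluripotency, on gelatin and Matrigel (-3.03 ± 0.44 and -2.71 ± 0.44). Of 11 LIF and STAT3 targets, 0 rose, 6 fell and 5 did not pass in embryoid bodies, 0, 5 and 6 on gelatin, and 0, 5 and 6 on Matrigel (adjusted over the list alone, 1, 0 and 0 higher and 7, 5 and 6 lower). The medians were -0.74, -0.45 and -0.71, with adjusted p = 0.000519, 0.00133 and 0.000214, and adjusted p = 0.0589, 0.0705 and 0.0437 with an estimated correlation. The homeobox gene Gbx2 fell in each condition (-1.04 ± 0.13, -0.97 ± 0.13 and -1.09 ± 0.13). Of 11 germ cell genes, 1 rose, 6 fell and 4 did not pass in embryoid bodies, 0, 6 and 5 on gelatin, and 0, 6 and 5 on Matrigel. The medians were -0.50, -0.54 and -0.46, with adjusted p = 0.00436, 0.00301 and 0.00362, and 0.136, 0.0909 and 0.107 with the session as a block. The falling members Rhox5 (-2.05 ± 0.34 in embryoid bodies) and Tex14 (-1.49 ± 0.13) are known from the testis, and Rhox5 also from embryonic stem cells. Of 13 epiblast genes, 0 rose, 5 fell and 8 did not pass in embryoid bodies, 0, 2 and 11 on gelatin, and 0, 2 and 11 on Matrigel (adjusted over the list alone, 2, 0 and 0 higher and 5, 2 and 2 lower). The medians were -0.12, -0.32 and -0.25, with adjusted p = 0.0537, 0.105 and 0.0771, and 0.0382 with the experiment as a block in embryoid bodies, and 0.032 with the doubted repeats left out in embryoid bodies. Pou3f1, a factor of the primed epiblast (-2.79 ± 0.66), and the Nodal antagonist Lefty1 (-2.47 ± 0.48, adjusted p = 0.000901, but 0.121 with the session as a block) fell in embryoid bodies.

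Of 18 cell cycle genes, 0 rose, 3 fell and 15 did not pass in embryoid bodies, 0, 2 and 16 on gelatin, and 0, 3 and 15 on Matrigel (adjusted over the list alone, 5, 3 and 3 lower). The medians were -0.31, -0.25 and -0.27, with adjusted p = 0.00018, 0.00138 and 0.000303, and adjusted p = 0.0971, 0.143 and 0.107 with an estimated correlation. The fall of Ccne1, the cyclin that starts DNA replication, held in every setting run (-1.87 ± 0.19 in embryoid bodies, -1.60 ± 0.19 on gelatin and -1.57 ± 0.19 on Matrigel). Of 15 stress response genes, 1 rose, 4 fell and 10 did not pass in embryoid bodies, 0, 6 and 9 on gelatin, and 0, 6 and 9 on Matrigel (adjusted over the list alone, 2, 0 and 3 higher and 6, 6 and 6 lower). The medians were -0.07, -0.04 and -0.01, with adjusted p = 0.0649, 0.0039 and 0.00407, and adjusted p = 0.0648 and 0.0648 with an estimated correlation on gelatin and on Matrigel. The chaperone Hsp90aa1 fell in embryoid bodies (-1.36 ± 0.18, adjusted p = 1.66e-05) and Chac1, which degrades glutathione, on Matrigel (-1.93 ± 0.39, adjusted p = 0.00236).

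Genes of connective tissue and matrix rose in all 3 conditions. Of 18 mesenchyme and smooth muscle genes, 11 rose, 0 fell and 7 did not pass in embryoid bodies, 10, 0 and 8 on gelatin, and 9, 0 and 9 on Matrigel (adjusted over the list alone, 13, 11 and 14 higher). The medians were 1.04, 1.24 and 0.96, with adjusted p = 2.96e-07, 4.99e-07 and 6.01e-07. Vim rose in embryoid bodies (3.35 ± 0.71), as did Tgfbi, a matrix protein induced by TGF-beta (3.08 ± 0.75). Cdh2, a cadherin of mesenchyme and neural tissue (2.08 ± 0.38), and Foxc1, a factor of paraxial mesoderm (1.75 ± 0.36), rose on Matrigel. Cdh11, a mesenchymal cadherin, was not well above background on any day 0 array and rose by at least 4.37-fold in embryoid bodies and at least 3.88-fold on gelatin. Of 9 fibroblast markers, 5 rose, 0 fell and 4 did not pass in embryoid bodies, 5, 0 and 4 on gelatin, and 3, 0 and 6 on Matrigel (adjusted over the list alone, 6, 5 and 4 higher). The medians were 0.89, 0.62 and 0.53, with adjusted p = 0.000137, 0.00118 and 0.00942, and adjusted p = 0.0202, 0.0292 and 0.0705 with an estimated correlation, and 0.434, 0.402 and 0.716 with the session as a block. The matrix protease Mmp2 rose in the 3 conditions (1.37 ± 0.16, 1.12 ± 0.16 and 1.03 ± 0.16). Of 15 parietal endoderm and basement membrane genes, 9 rose, 0 fell and 6 did not pass in embryoid bodies, 8, 0 and 7 on gelatin, and 9, 0 and 6 on Matrigel (adjusted over the list alone, 11, 10 and 9 higher). The medians were 0.89, 0.92 and 0.79, with adjusted p = 8.26e-05, 0.00011 and 0.000137, and adjusted p = 0.0705, 0.0705 and 0.073 with an estimated correlation. Sparc, a collagen-binding glycoprotein, rose in embryoid bodies and on gelatin (2.21 ± 0.52 and 2.16 ± 0.52), and the keratin Krt19 on gelatin (2.36 ± 0.57).

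Of 15 imprinted genes, 6 rose, 0 fell and 9 did not pass in embryoid bodies, 5, 0 and 10 on gelatin, and 4, 1 and 10 on Matrigel (adjusted over the list alone, 8, 5 and 4 higher and 0, 2 and 1 lower). The medians were 0.96, 0.40 and 0.18, with adjusted p = 0.00138, 0.0823 and 0.0613, and adjusted p = 0.0903 with an estimated correlation in embryoid bodies, and 0.0463 with the experiment as a block on Matrigel. Besides Igf2, the sarcoglycan gene Sgce rose (1.73 ± 0.29, 1.48 ± 0.29 and 1.37 ± 0.29), and Cdkn1c, an inhibitor of the cell cycle, in embryoid bodies (2.74 ± 0.47). Of 17 adhesion and contractility genes, 3 rose, 1 fell and 13 did not pass in embryoid bodies, 5, 0 and 12 on gelatin, and 4, 0 and 13 on Matrigel (adjusted over the list alone, 5, 5 and 7 higher and 1, 0 and 0 lower). The medians were 0.21, 0.08 and 0.26, with adjusted p = 0.267, 0.0352 and 0.00436, and adjusted p = 0.168 and 0.073 with an estimated correlation on gelatin and on Matrigel. Integrin Itgb5 rose on Matrigel (1.26 ± 0.20). Of 18 primitive streak and early mesoderm genes, 2 rose, 0 fell and 16 did not pass in embryoid bodies, 2, 0 and 16 on gelatin, and 2, 0 and 16 on Matrigel. The medians were 0.17, 0.50 and 0.55, with adjusted p = 0.239, 0.0223 and 0.00342, and adjusted p = 0.429 and 0.28 with an estimated correlation on gelatin and on Matrigel. The members that rose, Nkd1 (2.13 ± 0.27, 2.01 ± 0.27 and 1.65 ± 0.27) and Dkk1 (2.19 ± 0.42 on gelatin), are inhibitors of Wnt signalling found in many tissues and do not mark the streak by themselves. Of 17 p53 targets and cell cycle inhibitors, 2 rose, 1 fell and 14 did not pass in embryoid bodies, 3, 0 and 14 on gelatin, and 2, 0 and 15 on Matrigel (adjusted over the list alone, 3, 3 and 3 higher and 2, 1 and 1 lower). The medians were -0.13, 0.44 and 0.48, with adjusted p = 0.835, 0.0407 and 0.0313, and adjusted p = 0.429 and 0.394 with an estimated correlation on gelatin and on Matrigel. Btg2, an antiproliferative p53 target, rose on gelatin and Matrigel (1.18 ± 0.30 and 1.37 ± 0.30).

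Blood, endothelial and cardiac genes rose in embryoid bodies, with fewer of them past the threshold in the adherent cultures. Between conditions these lists were tested only in the means over days. Of 25 blood and endothelium genes, 17 rose, 0 fell and 8 did not pass in embryoid bodies, 1, 0 and 24 on gelatin, and 1, 0 and 24 on Matrigel. The medians were 0.85, 0.12 and 0.05, with adjusted p = 5.05e-10, 0.119 and 0.675, and adjusted p = 0.0589 with an estimated correlation in embryoid bodies. Besides the globins, Ramp2, a receptor partner of adrenomedullin in endothelium (3.24 ± 0.39), rose in embryoid bodies. The member that rose on gelatin and Matrigel was Flt1, a receptor of vascular growth factor (1.93 ± 0.36 and 2.03 ± 0.36). Of 22 cardiac muscle genes, 12 rose, 0 fell and 10 did not pass in embryoid bodies, 3, 0 and 19 on gelatin, and 0, 0 and 22 on Matrigel (adjusted over the list alone, 14, 3 and 0 higher). The medians were 0.85, 0.15 and 0.12, with adjusted p = 1.56e-06, 0.123 and 0.433, and adjusted p = 0.0971 with an estimated correlation in embryoid bodies. The troponin genes Tnnt2 (2.90 ± 0.56, adjusted p = 0.000863, but 0.128 with the session as a block) and Tnnc1 (1.78 ± 0.35, adjusted p = 0.00112) rose in embryoid bodies, and the actin Actc1 (1.04 ± 0.27, adjusted p = 0.0124, but 0.0817 without 1 sample) on gelatin. Of 9 extraembryonic endoderm regulators, 4 rose, 0 fell and 5 did not pass in embryoid bodies, 1, 0 and 8 on gelatin, and 1, 0 and 8 on Matrigel (adjusted over the list alone, 4, 1 and 1 higher and 1, 0 and 0 lower). The medians were 0.96, 0.50 and 0.38, with adjusted p = 0.0398, 0.123 and 0.298, and adjusted p = 0.113 with an estimated correlation in embryoid bodies. Sox7, shared by this endoderm and early endothelium, rose in embryoid bodies (1.12 ± 0.20, adjusted p = 0.00047, but 0.303 with the session as a block).

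By camera the other lists passed no test at day 7 except cholesterol synthesis on gelatin, while fry called some. Of 18 visceral endoderm genes, 4 rose, 1 fell and 13 did not pass in embryoid bodies, 3, 0 and 15 on gelatin, and 3, 1 and 14 on Matrigel. The medians were 0.22, 0.18 and 0.10, with adjusted p = 0.149, 0.0823 and 0.168. The protease Lgmn (1.51 ± 0.24 and 1.23 ± 0.24) and the coregulator Cited1 (1.05 ± 0.22 and 1.14 ± 0.22), neither specific to this tissue, rose on gelatin and Matrigel. Of 22 neural genes, 2 rose, 2 fell and 18 did not pass in embryoid bodies, 2, 2 and 18 on gelatin, and 2, 4 and 16 on Matrigel. The medians were -0.02, 0.01 and -0.004, with adjusted p = 0.885, 0.98 and 0.903. Lhx2, a factor of forebrain and eye, rose in embryoid bodies (1.04 ± 0.12) and Stmn2, a tubulin regulator of neurons, fell (-1.09 ± 0.23). The trophoblast list had medians of 0.04, 0.05 and 0.12 (adjusted p = 0.822, 0.298 and 0.0613). Hypoxia and glycolysis had medians of 0.32, 0.20 and 0.07 (adjusted p = 0.479, 0.558 and 0.85). Of 14 cholesterol synthesis genes, 0 rose, 0 fell and 14 did not pass in embryoid bodies, 2, 0 and 12 on gelatin, and 2, 0 and 12 on Matrigel (adjusted over the list alone, 0, 3 and 2 higher). The medians were 0.17, 0.39 and 0.21, with adjusted p = 0.168, 0.0149 and 0.119, and adjusted p = 0.316 with an estimated correlation on gelatin.

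Of 20 Hox genes, 1 rose in each condition. In embryoid bodies it was Hoxb5 (0.65 ± 0.17, adjusted p = 0.011, but up to 0.736 with the session as a block and 0.0522 without 1 sample). On Matrigel it was Hoxa13 (0.30 ± 0.09, adjusted p = 0.042, but up to 0.283 with series matrix values and 0.278 without 1 sample). Hoxa13 turned to -0.10 with median centring (adjusted p = 0.736). The Hox list gave adjusted p = 0.0815, 0.0624 and 0.0565 in these conditions, 0.0235, 0.0126 and 0.00938 with the Feature Extraction ratio, and 0.0303 in embryoid bodies with the doubted repeats left out. With that ratio the visceral endoderm list passed in embryoid bodies and on gelatin (0.0485 and 0.0447), the imprinted list on gelatin and Matrigel (0.0343 and 0.0267) and the cardiac list on gelatin (0.0386). Of 9 macrophage markers 0 changed with limma, and the list gave adjusted p = 0.558, 0.972 and 0.708. Of the list members eligible for naming, 46 of 71 in embryoid bodies, 33 of 61 on gelatin and 32 of 59 on Matrigel kept their call whichever sample was left out. Day 0 and day 7 shared 0 extraction sessions in embryoid bodies and on gelatin and 1 on Matrigel, where the pluripotency list had a median of -1.59.

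In each condition more genes differed from day 0 at day 7 than at day 3. In embryoid bodies 188 genes rose and 239 fell by day 3 (427 in total, 914 with the experiment as a block and 185 to 226 without either of 2 samples). By day 5, 950 genes rose and 804 fell (1754, 2985 with that block and 974 to 1104 without any of 3 samples), and by day 7, 1853 genes rose and 1095 fell (2948). On gelatin 61 genes rose and 165 fell by day 3 (226, 447 with that block and 103 to 141 without any of 3 samples). By day 5, 411 genes rose and 507 fell (918, 2099 with that block and 341 to 470 without any of 3 samples), and by day 7, 1422 genes rose and 890 fell (2312, 3824 with that block and 1377 to 1498 without either of 2 samples). On Matrigel 79 genes rose and 187 fell by day 3 (266, 646 with that block and 109 to 126 without either of 2 samples). By day 5, 940 genes rose and 571 fell (1511, 2813 with that block and 686 to 852 without any of 3 samples), and by day 7, 1216 genes rose and 904 fell (2120, 3490 with that block and 1223 without replicate 6 of day 0). The share that rose moved by more than 10 points with median centring, from 54.2% to 68.9% in embryoid bodies at day 5 and from 62.9% to 73.1% at day 7, from 44.8% to 32.1% on gelatin at day 5 and from 61.5% to 77% at day 7, and from 29.7% to 46.7% on Matrigel at day 3 and from 57.4% to 70.6% at day 7.

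Many changes at day 7 were common to all 3 conditions. In all 3, 811 genes rose and 632 fell, of 3707 that changed in at least 1, and 1477 changed in exactly 1. Embryoid bodies and gelatin shared 1051 rises (129 by chance) and 699 falls (47.8 by chance), with r = 0.851 across genes. Embryoid bodies and Matrigel shared 883 rises (110 by chance) and 758 falls (48.5 by chance), with r = 0.811. Gelatin and Matrigel shared 1018 rises (84.8 by chance) and 707 falls (39.4 by chance), with r = 0.948. In each pair 0 genes were called in opposite directions. The 3 day 0 samples are common to all, and simulated unchanged groups against them gave a mean r of 0.498 and a covariance of 0.0183 over 100 simulations, with 0 genes called in both. These simulations have no correlation between samples of the same experiment, which the data show. The measured covariances were 0.162, 0.147 and 0.154 in the same order.

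Against gelatin, over the mean of days 3, 5 and 7, red cell and vessel genes were higher in embryoid bodies. These included the globins Hba-x (1.78 ± 0.31, adjusted p = 0.00359, but 0.104 with the session as a block), Hbb-bt (1.04 ± 0.15, adjusted p = 0.00123, but 0.0542 with the session as a block) and Hbb-bh1 (2.26 ± 0.54, adjusted p = 0.0272, but up to 0.553 with the session as a block and 0.1 without 1 sample). Ramp2 (1.73 ± 0.23, adjusted p = 0.000339) and Plpp3, a lipid phosphatase needed for vessel formation (1.15 ± 0.17, adjusted p = 0.00123), were higher too. So were Tenm4, a teneurin, Mical1, an actin oxidase, and Selenop, a selenium carrier (1.05 ± 0.19, 0.86 ± 0.18 and 0.94 ± 0.22). Lower in embryoid bodies were the annexin Anxa3 (-2.18 ± 0.39, adjusted p = 0.00572), Sfn, a p53 target of stratified epithelia (-1.95 ± 0.22, adjusted p = 9e-05), and Perp, a p53 target in desmosomes (-1.92 ± 0.33). Wnt6 (-1.80 ± 0.26) and the annexin Anxa1 (-1.81 ± 0.44) were lower as well. The interferon-induced genes Gbp3 (-1.71 ± 0.32) and Cxcl10 (-1.62 ± 0.25) were lower too. All 16 genes that met the naming rule, not all named here, had the same sign on 3 of 3 days.

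With the session as a block, 11 of the 16 missed the threshold (adjusted p from 0.0542 to 0.553), while Ramp2, Plpp3, Sfn, Anxa1 and Anxa3 passed. Selenop gave adjusted p = 0.0642 and Anxa1 0.0774 without the conflictingly labelled samples, and Anxa1 0.0567 with median centring. Of the 16, 13 held whichever sample was left out, while Selenop gave adjusted p up to 0.061 and Anxa1 up to 0.07 without 1 sample. In total 236 genes were higher and 293 lower (529). The total was 1246 with the experiment as a block, 973 with the doubted repeats left out, 288 to 345 without any of 8 samples and 798 without 1 other.

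**Figure D2:**
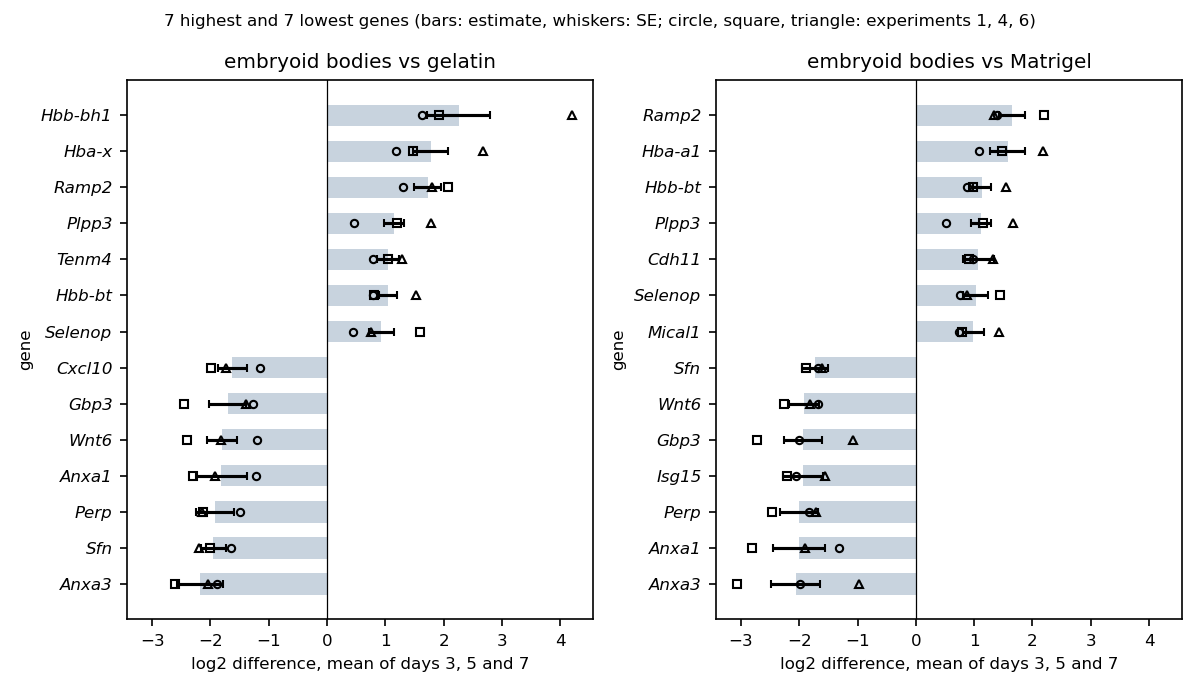
Difference in log2 expression between embryoid bodies and gelatin or Matrigel (horizontal axis, mean of days 3, 5 and 7) for the 7 highest and 7 lowest genes that met the naming rule (vertical axis), with bars for the estimate, whiskers for the standard error and symbols for experiments 1, 4 and 6. Ramp2 was 1.73 ± 0.23 against gelatin and 1.65 ± 0.23 against Matrigel, and Perp -1.92 ± 0.33 and -2.0 ± 0.33.

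Against Matrigel, embryoid bodies were again higher in genes of vessels and red cells. These were Ramp2 (1.65 ± 0.23, adjusted p = 0.000419), Plpp3 (1.12 ± 0.17), the globins Hba-a1 (1.58 ± 0.30, adjusted p = 0.00449) and Hbb-bt (1.13 ± 0.15, adjusted p = 0.00039), and Etv2, the factor that specifies blood and endothelial progenitors (0.96 ± 0.14, adjusted p = 0.000525). Selenop (1.03 ± 0.22), Mical1 (0.99 ± 0.18) and the mesenchymal cadherin Cdh11 (1.07 ± 0.27, adjusted p = 0.0271, but up to 0.116 with the Feature Extraction ratio and 0.0676 without 1 sample) were higher as well. Lower in embryoid bodies were Anxa3 (-2.06 ± 0.42, adjusted p = 0.008), Anxa1 (-2.01 ± 0.44, adjusted p = 0.0108), Perp (-2.0 ± 0.33) and Sfn (-1.73 ± 0.22), and Wnt6 (-1.92 ± 0.26). The interferon-induced Isg15 (-1.94 ± 0.34, adjusted p = 0.00232) and Gbp3 (-1.94 ± 0.32, adjusted p = 0.00158) were lower too. The session as a block kept all 16 that met the rule, and 15 of the 16 held whichever sample was left out. In total 255 genes were higher and 406 lower (661). It came to 1371 with the experiment as a block, 1349 with the doubted repeats left out and 414 without replicate 4 of Matrigel day 3. With median centring the share that was higher moved from 38.6% to 22.3%.

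Blood and endothelium genes were higher in embryoid bodies in these means. Of 25 blood and endothelium genes, 11 were higher, 0 lower and 14 did not pass against gelatin, and 10, 0 and 15 against Matrigel (adjusted over the list alone, 14 and 17 higher). The medians were 0.46 and 0.30, with adjusted p = 9.06e-14 and 1.53e-14. The globin Hbb-y stood at 1.38 ± 0.29 and 1.30 ± 0.29. Within the 3 sessions with both groups on a day, medians against gelatin were 0.82, 0.03 and 0.91 (days 7, 3 and 7). Against Matrigel they were 0.04, 0.19 and 0.74 (days 5, 3 with 5, and 5). The same days apply to session medians below, and none covers all 3. Targets of p53 were lower. Of 17 p53 targets and cell cycle inhibitors, 0 were higher, 7 lower and 10 did not pass against gelatin, and 0, 8 and 9 against Matrigel (adjusted over the list alone, 2 and 1 higher and 11 and 11 lower). The medians were -0.45 and -0.48, with adjusted p = 1.27e-08 and 4.35e-10. Phlda3, a p53 target that restrains Akt, was -1.18 ± 0.19 and -1.13 ± 0.19, and Pmaip1, a p53 target that promotes cell death, -1.04 ± 0.23 and -0.99 ± 0.23. Session medians were -0.67, -0.42 and -0.54 against gelatin and -0.35, -0.58 and -0.81 against Matrigel. Of 17 adhesion and contractility genes, 0 were higher, 3 lower and 14 did not pass against gelatin, and 0, 6 and 11 against Matrigel (adjusted over the list alone, 1 and 1 higher and 6 and 8 lower). The medians were -0.30 and -0.22, with adjusted p = 7.3e-06 and 4.76e-07. Ccn1, a matrix signal induced by cell tension, was -0.75 ± 0.16 and -0.81 ± 0.16. Session medians were -0.16, -0.05 and 0.01 against gelatin, so 1 of 3 was above 0, and -0.29, -0.28 and -0.50 against Matrigel.

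Of 22 cardiac muscle genes, 0 were higher, 0 lower and 22 did not pass against gelatin, and 0, 0 and 22 against Matrigel (adjusted over the list alone, 0 and 1 higher). The medians were 0.19 and 0.24, with adjusted p = 0.000232 and 3.71e-05, and adjusted p = 0.193 and 0.143 with an estimated correlation. The largest values were those of Myl7, an atrial myosin light chain (1.22 ± 0.55 and 1.47 ± 0.55). Of 18 mesenchyme and smooth muscle genes, 0 were higher, 2 lower and 16 did not pass against gelatin, and 1, 2 and 15 against Matrigel (adjusted over the list alone, 2 and 1 higher and 2 and 2 lower). The medians were 0.17 and 0.02, with adjusted p = 0.00589 and 0.0818, and adjusted p = 0.204 with an estimated correlation against gelatin, and 0.00306 with the doubted repeats left out against Matrigel. Cnn1, a calponin of smooth muscle, was lower (-1.38 ± 0.24 and -1.09 ± 0.23). Of 19 hypoxia and glycolysis genes, 0 were higher, 1 lower and 18 did not pass against gelatin, and 1, 1 and 17 against Matrigel (adjusted over the list alone, 0 and 5 higher and 1 and 1 lower). The medians were 0.23 and 0.36, with adjusted p = 0.0323 and 5.61e-05, and adjusted p = 0.524 and 0.221 with an estimated correlation. Of 20 pluripotency genes, 0 were higher, 3 lower and 17 did not pass against gelatin, and 0, 4 and 16 against Matrigel (adjusted over the list alone, 5 and 5 lower). The medians were -0.04 and -0.04, with adjusted p = 0.00436 and 0.0441, and adjusted p = 0.13 and 0.28 with an estimated correlation. The lower Spp1 (-1.29 ± 0.21 and -1.19 ± 0.21) and Klf5 (-0.89 ± 0.19 and -0.88 ± 0.19) are also expressed in epithelia. The adjusted p-values against gelatin and Matrigel were 0.00354 and 0.0125 for imprinted genes, 0.00873 and 0.00345 for LIF and STAT3 targets, 0.0613 and 0.00191 for fibroblast markers and 0.0444 and 0.0613 for extraembryonic endoderm. With an estimated correlation they were adjusted p = 0.116 and 0.169, 0.135 and 0.0971, 0.0331 for fibroblast markers against Matrigel and 0.12 for extraembryonic endoderm against gelatin. The last was also lost with the experiment as a block (0.0518), the Feature Extraction ratio (0.0503) and the doubted repeats left out (0.087), and the fibroblast test against Matrigel with the session as a block (0.463). Against gelatin the fibroblast list passed with the doubted repeats left out (0.0125), and against Matrigel the extraembryonic endoderm list with the Feature Extraction ratio (0.0447).

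**Figure D3:**
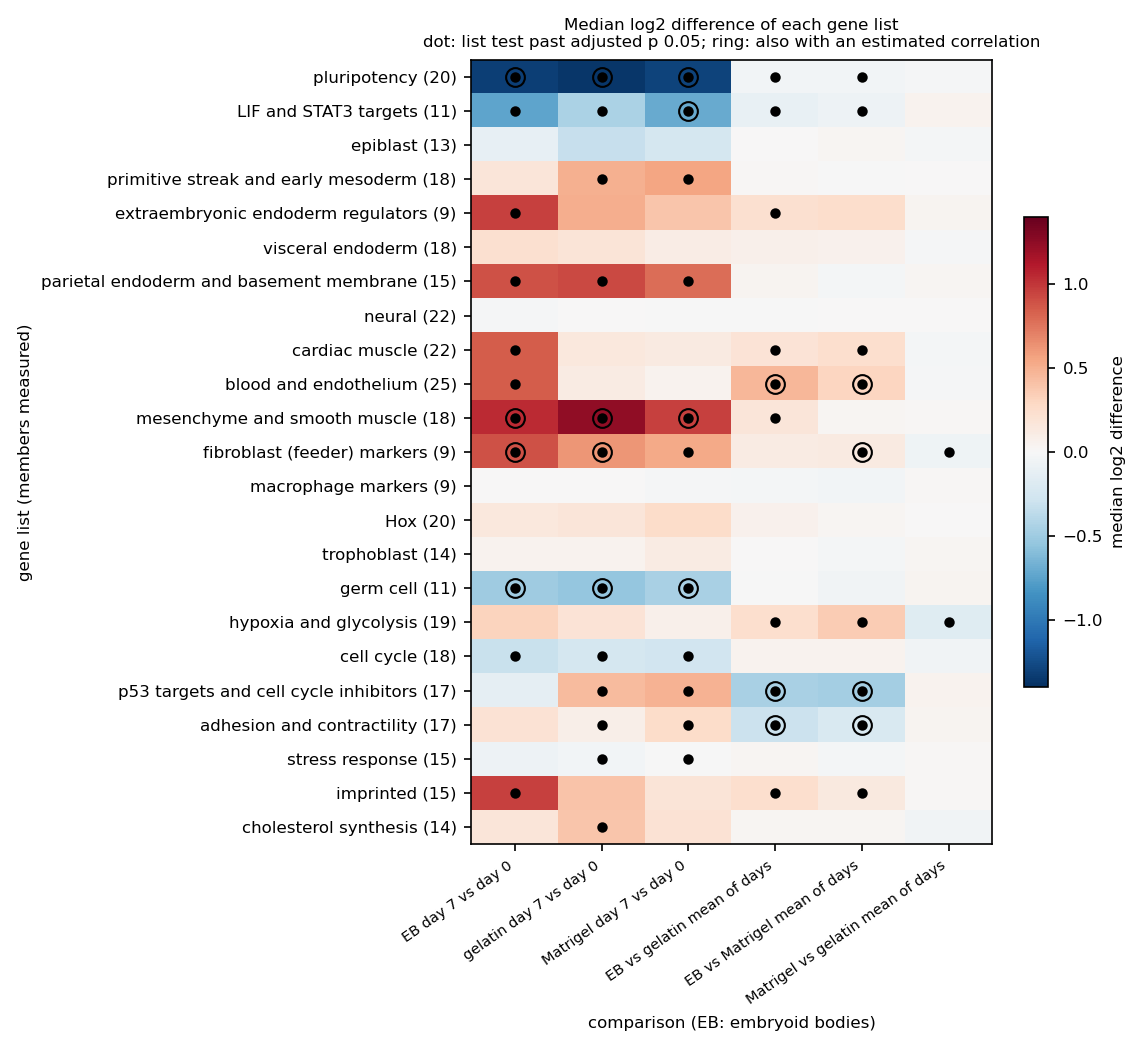
Median log2 difference of each gene list (colour) in 6 comparisons (columns), with the lists as lines, dots for tests past an adjusted p of 0.05 and rings for those also past it with an estimated correlation. The blood and endothelium list had a median of 0.85 in embryoid bodies at day 7 against day 0 and 0.12 on gelatin, and the pluripotency list -1.32 and -1.36.

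The other 12 lists gave adjusted p-values from 0.115 to 0.987 in these means, and the Hox list 0.0487 against Matrigel with the doubted repeats left out. Cited1, of the visceral endoderm list, was lower (-0.78 ± 0.13 and -0.83 ± 0.13). Of the list members eligible for naming, 19 of 30 against gelatin and 21 of 35 against Matrigel kept their call whichever sample was left out. With the session as a block, 28 and 8 of them missed the threshold.

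On single days, embryoid bodies and gelatin differed at days 5 and 7. At day 5 Ramp2 (2.09 ± 0.39, adjusted p = 0.0203), Plpp3 (1.69 ± 0.29, adjusted p = 0.0124) and Cbln1, a synaptic organizer (1.33 ± 0.26, adjusted p = 0.0271), were higher. Lower in embryoid bodies were Sfn (-2.54 ± 0.38, adjusted p = 0.00405), Wnt6 (-2.37 ± 0.44, adjusted p = 0.0203) and Lefty1 (-2.34 ± 0.48, adjusted p = 0.0324). The session as a block ended all 6 calls (adjusted p from 0.0635 to 0.263), but these groups shared no session to compare within. Sfn held whichever sample was left out, and the other 5 gave adjusted p up to 0.173 without 1 sample. In total 34 genes were higher and 53 were lower (87). This became 553 with the experiment as a block, 197 with the doubted repeats left out, 6 to 19 without any of 4 samples and 282 to 340 without either of 2 samples. With median centring the share that was higher moved from 39.1% to 50.5%. At day 7 Hba-x (3.75 ± 0.53, adjusted p = 0.00131) and Hbb-y (3.51 ± 0.50, adjusted p = 0.00131) were higher whichever sample was left out. Postn (2.66 ± 0.58, adjusted p = 0.0409, but up to 0.227 with median centring and 0.24 without 1 sample) was higher as well. Lower were Psmb8 (-2.25 ± 0.50, adjusted p = 0.047) and Irgm1 (-1.94 ± 0.35, adjusted p = 0.0168), both induced by interferon, and Pmaip1 (-1.86 ± 0.40, adjusted p = 0.0359). These 3 missed the threshold without 1 sample (adjusted p up to 0.261, 0.118 and 0.203). With the session as a block 4 of the 6 missed it (0.101 to 0.329), without the conflicting labels 4 (0.102 to 0.293) and with median centring 3 (0.105 to 0.227). In total 72 genes were higher and 18 were lower (90). The number was 187 with the experiment as a block, 314 with the doubted repeats left out, 15 with median centring, 13 to 36 without any of 4 samples and 201 without replicate 6 of embryoid bodies day 7. The share that was higher moved from 80% to 61.1% with the Feature Extraction ratio. At day 3, 0 genes passed, and 719 had an unadjusted p under 0.05, fewer than by chance. The experiment as a block gave 5, and leaving out either of 2 samples 5 to 8.

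Against Matrigel, Ramp2 (2.41 ± 0.39, adjusted p = 0.0024) and Spink1 (3.08 ± 0.72, adjusted p = 0.0203, but 0.156 without 1 sample), a trypsin inhibitor, were higher in embryoid bodies at day 5. Cdh11 (1.73 ± 0.47, adjusted p = 0.0468, but up to 0.224 with the Feature Extraction ratio and 0.206 without 1 sample) was higher too. Perp (-3.17 ± 0.57, adjusted p = 0.00375), Gbp3 (-2.97 ± 0.55, adjusted p = 0.00462) and Wnt6 (-2.95 ± 0.44, adjusted p = 0.00194) were lower. In total 174 genes were higher and 384 were lower (558). It was 1289 with the experiment as a block and 175 to 339 without any of 5 samples. At day 7 the embryonic globins Hbb-bh1 (4.97 ± 0.86, adjusted p = 0.00616), Hba-x (4.21 ± 0.53, adjusted p = 0.000243) and Hbb-y (3.73 ± 0.50, adjusted p = 0.000412) were higher whichever sample was left out, although Hbb-bh1 gave adjusted p = 0.205 with series matrix values. Isg15 (-2.93 ± 0.59, adjusted p = 0.0125, but 0.217 with the session as a block and 0.102 without 1 sample) was lower. So were Psmb8 (-2.53 ± 0.50, adjusted p = 0.0115, but 0.563 with the session as a block and 0.0991 without 1 sample) and Gbp3 (-2.40 ± 0.55, adjusted p = 0.0322, but up to 0.54 with the session as a block and 0.192 without 1 sample). With the session as a block 5 of the 6 missed the threshold (0.0564 to 0.563), and Hba-x passed. These groups shared no session. In total 135 genes were higher and 64 were lower (199). This total was 371 with the experiment as a block, 489 with the doubted repeats left out, 49 to 104 without any of 3 samples and 325 without replicate 6 of embryoid bodies day 7. The share that was higher moved from 67.8% to 53.9% with the Feature Extraction ratio. At day 3, 0 genes passed, and 1085 had an unadjusted p under 0.05, about as many as by chance. The experiment as a block gave 5, and leaving out either of 2 samples 2 to 10.

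Between Matrigel and gelatin, 0 genes passed with limma on any day or in the mean. Unadjusted p-values under 0.05 (430, 601 and 457 on days 3, 5 and 7, 257 in the mean) were fewer than by chance. The experiment as a block also gave 0. Leaving out 1 sample gave up to 2, 6 and 1 on these days and 4 in the mean. Of the lists, hypoxia and glycolysis was lower on Matrigel (median -0.17, adjusted p = 0.00106, adjusted p = 0.348 with an estimated correlation) and so were the fibroblast markers (median -0.06, adjusted p = 0.0448, adjusted p = 0.143 with an estimated correlation, 0.0582 with the experiment as a block, 0.0753 with the Feature Extraction ratio). In both, 0 members passed, and the largest differences were -0.62 for Ddit4, a stress-induced inhibitor of growth signalling, and -0.38 for Postn. The epiblast list gave adjusted p = 0.0692, 0.0489 with the experiment as a block, the cell cycle list adjusted p = 0.0695, 0.0462 with the experiment as a block, the trophoblast list adjusted p = 0.0741, 0.024 with the Feature Extraction ratio, and the blood list adjusted p = 0.762, 0.00256 with the doubted repeats left out. The other lists gave adjusted p-values between 0.119 and 0.978. Samples of the same day in these groups shared 0 extraction sessions.

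From day 3 to day 7 in embryoid bodies, the globins Hbb-bh1 (6.04 ± 0.86, adjusted p = 0.000522) and Hba-x (4.40 ± 0.53, adjusted p = 9.88e-05) and the matrix gene Postn (5.29 ± 0.58, adjusted p = 6.18e-05) rose. Slc7a3 fell (-2.46 ± 0.39, adjusted p = 0.000662), with Dppa5a (-2.67 ± 0.62, adjusted p = 0.0112, but 0.0834 without 1 sample) and the DNA methyltransferase Dnmt3b (-3.28 ± 0.79, adjusted p = 0.0142, but 0.075 without 1 sample). In total 752 genes rose and 373 fell (1125). The sum was 2515 with the experiment as a block, 1782 with the doubted repeats left out and 609 to 636 without any of 3 samples. On gelatin Spink1 (3.94 ± 0.72, adjusted p = 0.00667), Pmp22 (3.71 ± 0.74, adjusted p = 0.0105, but 0.0644 without 1 sample) and Igf2 (3.42 ± 0.60, adjusted p = 0.00611) rose. Slc7a3 (-2.93 ± 0.39, adjusted p = 0.00091), Lefty1 (-2.46 ± 0.48, adjusted p = 0.00886, but 0.119 with the session as a block and 0.0594 without 1 sample) and Pou5f1 (-1.76 ± 0.36, adjusted p = 0.012, but 0.229 with the session as a block and 0.0868 without 1 sample) fell. In total 373 genes rose and 190 fell (563). The sum became 1689 with the experiment as a block and 104 to 327 without any of 6 samples. With median centring the share that rose moved from 66.3% to 77.2%.

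On Matrigel Usp18, which removes Isg15 from proteins, rose from day 3 to day 7 (2.2 ± 0.32, adjusted p = 0.00495) under every setting run. Isg15 (2.89 ± 0.59, adjusted p = 0.0303, but up to 0.0805 with series matrix values and 0.181 without 1 sample) and Spink1 (3.33 ± 0.72, adjusted p = 0.0389, but up to 0.163 with the conflicting labels left out and 0.174 without 1 sample) rose as well. Slc7a3 (-1.93 ± 0.39, adjusted p = 0.0303, but 0.163 with the conflicting labels left out and 0.166 without 1 sample) fell. So did Bok (-1.60 ± 0.31, adjusted p = 0.02, but up to 0.232 with the session as a block and 0.139 without 1 sample), a regulator of cell death. Rspo1 (-1.25 ± 0.21, adjusted p = 0.00912, but up to 0.0736 with the conflicting labels left out and 0.0614 without 1 sample), an enhancer of Wnt signalling, fell too. In total 44 genes rose and 39 fell (83). The sum came to 411 with the experiment as a block, 424 with the doubted repeats left out and 6 to 43 without any of 5 samples.

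The condition by day interaction asked which genes' courses differed between conditions, and 1 passed. Thsd1, a membrane protein of endothelium, had an adjusted p of 0.0359 (0.0334 with the experiment as a block, where 8 genes passed). At day 7 it stood at 0.65 ± 0.30 over the reference in embryoid bodies (SD, n = 3), -0.62 ± 0.17 on gelatin and -0.86 ± 0.07 on Matrigel, beside -0.51 ± 0.05 at day 0. The call ended with the Feature Extraction ratio (0.299), series matrix values (0.133), median centring (0.0784), the session as a block (0.425) and the conflicting labels left out (0.116). It ended without any of 16 samples, with an adjusted p of up to 0.149 without replicate 4 of embryoid bodies day 3. The count was 0 without any of 14 samples and 3 to 41 without any of 9 others.

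Many calls that the session as a block ended, such as those of Perp and Wnt6 against gelatin in the mean, passed when the 2 doubted repeat arrays were also left out, a fit chosen after the data were seen. With these arrays the session fit of single genes gave a correlation of -0.539 between arrays of the same sample, so repeats counted as less alike than unrelated arrays, and without them 0.309. It ended 131 called values of named genes and stage markers, of which 88 passed without these arrays. Pou5f1 at day 7 was among those that passed (0.0547 and 0.0687 with the session as a block in embryoid bodies and on gelatin, 0.00074 and 0.00475 without these arrays). So were Pou5f1 at day 5 in embryoid bodies (0.00551), Lefty1 (7.33e-06) and Tnnt2 (0.00328) in embryoid bodies at day 7, Pou5f1 (0.0473) and Lefty1 (0.000311) on gelatin and Bok (0.00136) on Matrigel from day 3 to day 7, and Thsd1 in the interaction (0.033). T at day 3 in embryoid bodies newly passed (0.0312). Pou5f1 at day 5 on Matrigel (0.104), and Sox7 (0.0512) and Hoxb5 (0.144) in embryoid bodies at day 7, still missed the threshold. Of the genes named by size against gelatin, 2 of 16 missed it in the mean (Hbb-bh1 and Selenop), 4 of 6 at day 5 (Plpp3, Cbln1, Wnt6 and Sfn) and 0 of 6 at day 7, and against Matrigel 0 of 6 at day 7. The count against gelatin in the mean was 85 with the session as a block and 735 without these arrays. Of the 55 list tests past the threshold, 25 passed with the session as a block and 46 without these arrays. The fibroblast list passed there at day 7 in embryoid bodies and on gelatin (0.00155 and 0.0146) but not on Matrigel (0.0915), and in the mean against Matrigel (0.00155). The other 8 that did not pass were germ cells at day 7 (0.171, 0.135 and 0.225), extraembryonic endoderm in embryoid bodies at day 7 and against gelatin (0.171 and 0.262), pluripotency against gelatin and Matrigel (0.13 and 0.0629) and LIF and STAT3 targets against gelatin (0.0989).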

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

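The tests of the repeat arrays, of the software version, of exchanged labels, of compression as the whole cause and of splits within experiments were chosen only after the result was seen. Thsd1 was the 1 gene to pass the condition by day interaction test (adjusted p = 0.0359). Of 41 genes examined, Anxa3 was lower at day 7 than at day 0 in each experiment of embryoid bodies (-0.51, -0.49 and -0.10 in experiments 1, 4 and 6, log2) and higher in each on gelatin (1.20, 0.99 and 1.28), a difference of -1.71, -1.48 and -1.38 within experiments. Over all genes the test at day 7 did not pass (-1.53 ± 0.68, adjusted p = 0.603), nor did it with the experiment as a block (-1.52 ± 0.47, adjusted p = 0.142).

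Repeat arrays of 2 samples of experiment 6, from the same extraction session, were unlike their first arrays. The repeat labelled Matrigel day 3 correlated with its first array at r = 0.11, where the other 4 repeat pairs reached 0.54 or more, which argues against noise between repeats. It correlated with the first array of embryoid bodies day 7 at r = 0.86, so an array carrying another sample stays open and may explain it. For the repeat labelled embryoid bodies day 7, r = 0.29 away from its noisy edge argues against an edge defect, and r = 0.73 with the Matrigel day 3 first array, below the 0.86 with Matrigel day 5, leaves open a swap between these 2 arrays. No biological explanation was tested, and both arrays kept their labels.

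Each sample was placed on the day 3 to day 7 axis of the other experiments. Day 5 of experiment 1 lay at 0.13 in embryoid bodies, -0.07 on gelatin and 0.15 on Matrigel (others 0.55 to 0.92). Its day 7 lay at 0.65, 0.49 and 0.64 (others 0.88 to 1.1), day 3 at -0.038, -0.12 and 0.079 (others 0.014 to 0.35). The older software version of experiment 1 is argued against by its day 5 repeat arrays, extracted with the newer version, at 0.10 and 0.08, and exchanged day 3 and day 5 labels by day 3 samples at 0.079 or less. Compressed ratios are not excluded by the test planned for them, since in 1 of 3 conditions, not 2, day 5 of experiment 1 correlated better with day 3 than with day 5 of the others. As the whole cause compression is argued against, since day 5 of experiment 1 correlated better with day 3 than with day 7 in 3 of 3 conditions and the others in 0 of 6. Slower differentiation in experiment 1, or in part an offset of all its days, stays open and was not tested.

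Other splits of the samples tested the counts. In 3 v 3 comparisons the 10 splits are too few for a share under 0.05. The real split gave the most genes (1 of 10) in 16 of these 21, where the highest other was 34 against 2948 in embryoid bodies at day 7, 36 against 90 for embryoid bodies and gelatin at day 7, 22 against 199 for embryoid bodies and Matrigel at day 7 and at most 2 against 83 to 2312 in the other 13. In 5 comparisons all 10 gave 0, and among the 4 splits that part all pairs of an experiment number the highest other was 2. In the means over days chance can be excluded for embryoid bodies against gelatin (1 of 100 splits as large, 529 genes, highest other 78) and against Matrigel (2 of 100, 661 genes, highest other 663 in a split that kept 8 of 9 embryoid body samples together). For Matrigel against gelatin 100 of 100 gave at least the real 0. Its highest, 1213, had all 6 samples of experiment 1 on 1 side, which points to a structure of the samples by experiment, and the real count was also 0 with the experiment as a block. For the interaction 32 of 100 gave at least the real 1 gene, up to 331, so chance is not excluded and the samples again show structure. For the list tests 1 of 100 splits gave as many as the real 55 (highest other 52), and 2 of 100 did when labels were drawn within each experiment (highest other 61). Both shares lie under 0.05, so random labels are an unlikely source of this count. Of these splits 26 and 46 gave above 0.5 of it. Single list p-values may be too small, but these splits cannot tell. Their groups mix days and so carry changes over time.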

How the results depend on the processing

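Without the 2 doubted repeat arrays, an alternative chosen after the data were seen, the counts that moved by more than 1.5 times were 197, 314 and 973 for embryoid bodies v gelatin at days 5 and 7 and in the mean, and 1, 489 and 1349 for embryoid bodies v Matrigel at days 3 and 7 and in the mean. It also gave 1782 and 424 from day 3 to day 7 in embryoid bodies and Matrigel, and 21 in the interaction. With the first array only they were 220, 315 and 926 for embryoid bodies v gelatin at days 5 and 7 and in the mean, and 1, 478 and 1263 for embryoid bodies v Matrigel at days 3 and 7 and in the mean. Further counts were 1699 and 377 from day 3 to day 7 in embryoid bodies and Matrigel, and 27 in the interaction. Both settings leave out arrays. With the experiment as a block the moved counts were 914 and 2985 in embryoid bodies at days 3 and 5, and 447, 2099 and 3824 on gelatin at days 3, 5 and 7. The setting also gave 646, 2813 and 3490 on Matrigel at days 3, 5 and 7, and 5, 553, 187 and 1246 for embryoid bodies v gelatin at days 3, 5 and 7 and in the mean. Other moved counts were 5, 1289, 371 and 1371 for embryoid bodies v Matrigel at days 3, 5 and 7 and in the mean, 2515, 1689 and 411 from day 3 to day 7 in embryoid bodies, gelatin and Matrigel, and 8 in the interaction. The block changed no other call on a count. With median centring they were 213, 1086 and 1549 in embryoid bodies at days 3, 5 and 7, and 68, 209 and 1531 on gelatin at days 3, 5 and 7. It also gave 167, 696 and 1308 on Matrigel at days 3, 5 and 7, and 15 and 232 for embryoid bodies v gelatin at day 7 and in the mean. Further counts were 268, 80 and 278 for embryoid bodies v Matrigel at days 5 and 7 and in the mean, 509, 92 and 11 from day 3 to day 7 in embryoid bodies, gelatin and Matrigel, and 0 in the interaction. In this setting Hoxa13 on Matrigel at day 7 turned from 0.30 to -0.103 (log2). With the session as a block, which spends 11 of the degrees of freedom, they were 1622 on gelatin at day 5, and 6 and 85 for embryoid bodies v gelatin at day 5 and in the mean. The setting also gave 1709, 23 and 1151 for embryoid bodies v Matrigel at days 5 and 7 and in the mean, and 5 for Matrigel v gelatin at day 7. Other moved counts were 358 from day 3 to day 7 in Matrigel, and 25 list tests. With that block and without the doubted repeat arrays, also chosen after the data were seen, they were 990 in embryoid bodies at day 3, 489 and 2397 on gelatin at days 3 and 5, and 426 and 2678 on Matrigel at days 3 and 5. The setting also gave 4, 18 and 801 for embryoid bodies v gelatin at days 3, 5 and 7, and 6, 1717, 300 and 2268 for embryoid bodies v Matrigel at days 3, 5 and 7 and in the mean. Further counts were 3 for Matrigel v gelatin at day 7, 2927, 1323 and 1040 from day 3 to day 7 in embryoid bodies, gelatin and Matrigel, and 18 in the interaction. A call of at least 2-fold lowers counts by construction, to 131, 529 and 893 in embryoid bodies at days 3, 5 and 7, and 76, 262 and 686 on gelatin at days 3, 5 and 7. It also gave 69, 472 and 583 on Matrigel at days 3, 5 and 7, and 42, 47 and 70 for embryoid bodies v gelatin at days 5 and 7 and in the mean. Further counts were 234, 101 and 89 for embryoid bodies v Matrigel at days 5 and 7 and in the mean, and 406, 165 and 32 from day 3 to day 7 in embryoid bodies, gelatin and Matrigel. Without the 2 samples with conflicting labels, so with fewer samples, they were 1391 on Matrigel at day 7, and 13 and 287 for embryoid bodies v gelatin at day 7 and in the mean. The setting also gave 130 for embryoid bodies v Matrigel at day 7, 1 and 1 for Matrigel v gelatin at day 7 and in the mean, and 224 and 26 from day 3 to day 7 in gelatin and Matrigel. Series matrix values gave 138 and 55 for embryoid bodies v gelatin at day 5 and day 7, and 2 for embryoid bodies v Matrigel at day 3. Other moved counts were 2 for Matrigel v gelatin at day 3, 44 from day 3 to day 7 in Matrigel, and 11 in the interaction. The Feature Extraction ratio gave 133 and 36 for embryoid bodies v gelatin at day 5 and day 7, and 102 for embryoid bodies v Matrigel at day 7. It also gave 40 from day 3 to day 7 in Matrigel, and 0 in the interaction. The strict filter, with fewer genes, gave 57 for embryoid bodies v gelatin at day 7, and 120 for embryoid bodies v Matrigel at day 7. Further counts were 55 from day 3 to day 7 in Matrigel, and 0 in the interaction. No background subtraction gave 52 for embryoid bodies v gelatin at day 5, and an estimated correlation 19 list tests. Except where arrays, samples or genes were fewer or a larger change was required, the cause was not tested.

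Leaving out 1 sample of the compared groups in turn gave 185 to 425, 974 to 1820 and 1994 to 2741 in embryoid bodies at days 3, 5 and 7, and 103 to 225, 341 to 1318 and 1377 to 2122 on gelatin at days 3, 5 and 7. The setting also gave 109 to 259, 686 to 1410 and 1223 to 1855 on Matrigel at days 3, 5 and 7, and 0 to 8, 6 to 340, 13 to 201 and 288 to 798 for embryoid bodies v gelatin at days 3, 5 and 7 and in the mean. Other moved counts were 0 to 10, 175 to 713, 49 to 325 and 414 to 962 for embryoid bodies v Matrigel at days 3, 5 and 7 and in the mean, and 0 to 2, 0 to 6, 0 to 1 and 0 to 4 for Matrigel v gelatin at days 3, 5 and 7 and in the mean. It also gave 609 to 1152, 104 to 327 and 6 to 109 from day 3 to day 7 in embryoid bodies, gelatin and Matrigel, and 0 to 41 in the interaction. The remaining samples of such a group are assumed to vary like the other groups, since limma pools the spread.

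Signal over background limits what can be seen: probes well above background on fewer than 3 arrays were not tested, and 13857 genes were left where both channels had to be well above background on all arrays. Of 510 values of named genes and stage markers, 489 kept their direction and side of the threshold with the Feature Extraction ratio, 429 with median centring, 498 with no background subtraction, 506 with no filter, 489 with the experiment as a block, 374 with the session as a block, 454 with that block and without the doubted repeat arrays, 485 with the first array only, 489 without the doubted repeat arrays and 510 with the mean of probes. The others had no value for some genes, and 469 of 506 kept them with series matrix values, 437 of 442 with the strict filter and 407 of 468 without the conflicting labels. With 1 sample left out, 4700 of 5358 values kept them, 603 missed the threshold and 55 newly passed. Of the called values among these, Hoxa13 alone turned its sign. Every alternative fixed before the data were examined was run, with the session as a single block for date and version.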

Other observations

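The list of interferon-response genes, and so the tests on it, were chosen only after the result was seen. Genes that respond to interferon, the signal of antiviral defence, were lower in embryoid bodies than in adherent cultures in the means over days. The report's naming rule had brought up 7 of them (Gbp3, Irgm1, Usp18, Psmb8, Rtp4, Cxcl10 and Isg15), and a list of 88 others, of which 50 were measured and 1 (Ifitm3) is also in the germ cell list, was tested. Against gelatin 7 were lower and 43 did not pass (median -0.16, adjusted p = 3.67e-15, adjusted p = 0.00543 with an estimated correlation), among them Irf1, a transcription factor of the response (-1.11 ± 0.22), Psmb10, a subunit of the immunoproteasome (-1.09 ± 0.22), and Gbp2, a guanylate-binding protein (-1.02 ± 0.18). Against Matrigel 17 were lower and 33 did not pass (median -0.28, adjusted p = 9.76e-21, adjusted p = 0.00219 with an estimated correlation), with Psmb10 (-1.15 ± 0.20), Gbp2 (-1.10 ± 0.18) and Ifi35, an interferon-induced protein (-1.06 ± 0.18). Both medians were below 0 in 3 of 3 experiments.

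By day 7 the response had risen against day 0 in the adherent cultures. On Matrigel 19 genes of the list rose and 1 fell (median 0.38, adjusted p = 2.07e-08, adjusted p = 0.0365 with an estimated correlation) and on gelatin 11 rose and 1 fell (median 0.23, adjusted p = 5.54e-05, adjusted p = 0.118 with an estimated correlation). B2m, the light chain of antigen-presenting molecules, rose by 2.26 ± 0.47 and 2.17 ± 0.47 and Irgm2, a GTPase of defence within cells, by 1.94 ± 0.36 and 1.65 ± 0.36. In embryoid bodies 2 rose and 4 fell (median 0.03, adjusted p = 0.418), and between Matrigel and gelatin the median was 0.07 (adjusted p = 0.000591, adjusted p = 0.16 with an estimated correlation).

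Macrophages in the adherent cultures are argued against as the whole cause. The medians of their 9 markers were -0.025 against gelatin and -0.04 against Matrigel (SD 0.049 and 0.056), which falls short of the interferon list by 0.135 or more. At day 7 against day 0 the markers stood at 0.001 on gelatin and -0.012 on Matrigel (SD 0.056 and 0.057), where the list rose. The markers reached 0.16 of the list's median against gelatin, with a spread that leaves a larger share open. Markers such as C1qa (-0.14 ± 0.04) and Csf1r (-0.09 ± 0.08) did not pass against gelatin. The extraction session is argued against, since with the session as a block the list passed in both comparisons (adjusted p = 3.67e-09 or less), also with 1 array per sample (9.99e-11 or less). Session medians (days as above) were -0.31, -0.04 and -0.36 against gelatin and -0.12, -0.18 and -0.35 against Matrigel. The list passed without the 7 genes seen first, so a response shared across interferon genes stays open. Attached cells may respond to an interferon signal which aggregated cells lack, and no test here measured such a signal.

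First arrays correlated at a median r of 0.53 within groups and 0.33 between groups. Over all 630 pairs of arrays the lowest r was -0.33, between embryoid bodies day 7 and day 0 of experiment 1.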
